A study of Mus musculus with 8 samples.

How the data were processed

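Bulk RNA sequencing was done on NK cells from the spleens of 8-week-old female mice of 2 inbred strains, NOD/ShiLtJ (called NOD here) and C57BL6/J (called C57BL6 here). NK cells are innate lymphocytes that kill infected or transformed cells. NOD mice develop autoimmune diabetes without treatment, and C57BL6 is the strain whose genome underlies the mouse reference sequence. Per the labels' protocols, NK cells were enriched with a bead kit that removes other cells, the enrichment was checked by flow cytometry for NKp46 and CD49b and for absence of CD3, and total RNA was sequenced as paired reads of 150 bases. Each strain had 4 libraries, carrying the numbers 2, 3, 4 and 6 for C57BL6 and 2, 3, 4 and 5 for NOD. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

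The file holds 1 row per gene for 16748 genes, with 8 columns of per-library values and the authors' own comparison. The per-library signal values deposited by the authors were gene counts divided by 1 factor per library: every value in a column was a whole multiple of the smallest value above 0, and 100% of values gave whole reads within a tolerance of 1e-06. The log2 fold change deposited by the authors is NOD over C57BL6, and its sign was checked against the strain means. The p-values in the authors' deposited table are an unadjusted and an adjusted p per gene, both missing for 10 genes. The build is mm10 per the submitters' processing notes. The aligner, the counting tool, its strand setting, its treatment of reads shared between genes, the annotation and the authors' test are not given in the sources used here, so the values of paralogous, overlapping and antisense genes are uncertain. The table was limited to expressed genes: the lowest mean normalized count of any gene was 9.14, and the lowest total over the 8 libraries was 81 reads.

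The recovered reads over the listed genes came to 11032645, 14961466, 12637190 and 10497210 in C57BL6 replicates 2, 3, 4 and 6, and to 8541693, 9887783, 10314163 and 9585600 in NOD replicates 2, 3, 4 and 5. These totals cover the listed genes only and are not full library depths. Factors computed from the recovered reads with DESeq2 1.42.0 matched the authors' factors to the 4 decimals compared, for example 1.0245 in C57BL6 replicate 2. The design fixed in advance named a count test for counts and limma for normalized values, and the limma branch was used because the deposited values are normalized. Genes at or above a value of 1 in at least 4 libraries were kept, which removed none. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (linear model with strain as its 1 factor, moderated variance with an intensity trend). P-values were adjusted by the Benjamini-Hochberg method over the 16748 genes, and genes under 0.05 were called. Fold changes are NOD over C57BL6 on the log2(value + 1) scale, which understates the change of genes with few reads. Means ± SD are of normalized counts, with n = 4 libraries per strain, and each ± after a fold change is its SE. For a gene with 0 reads in a strain, the fold was computed against 3 reads over that strain's libraries and is a lower bound. For a gene with 1 to 3 reads, the ratio of counts is given with a 95% exact interval. Both cover counting error only, since the reads carry no molecular identifiers.

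Lists of genes were fixed before the data were examined: NK cell identity, immature NK cells, mature NK cells, ILC1 and tissue-resident NK cells, cytotoxic granule, cytokines and chemokines, Ly49 receptors, NKG2 and NKR-P1 receptors and ligands, activating receptor signalling, inhibitory receptors and checkpoints, cytokine receptors and STATs, migration and adhesion, lymphocyte transcription factors, MHC class I and antigen processing, MHC class II, interferon-stimulated genes, genes named in NOD diabetes susceptibility loci, Fc and complement receptors, proliferation, immediate-early and handling stress, glycolysis, mitochondrially encoded, apoptosis and survival, cytosolic ribosomal proteins, and markers of T cells, B cells, plasma cells, monocytes and macrophages, neutrophils, dendritic cells, erythroid cells, megakaryocytes and platelets, basophils and mast cells, ILC2 and ILC3, stromal and endothelial cells, and haematopoietic progenitors. List members that are not in the table could not be counted. Since the table is limited by expression, a gene low in both strains is missing while one high in a single strain is kept, which favours changed genes in lists of rare cells. The 36 lists were tested with camera in limma at a preset correlation of 0.01, which asks whether a list moved relative to the other genes, with adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list moved on balance in 1 direction, were run beside it. Named genes followed a rule also fixed in advance. They are the 12 genes with the highest and the 12 with the lowest fold change among called genes with an average log2 value of at least 3, no overlap of the strains and a symbol that is not a predicted or pseudogene name. To these come up to 4 members of each list with the lowest adjusted p, and 14 genes named whatever their values. Other genes were chosen after their values were seen, and are named only as members of a list, of a region or of a short count.

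Gene positions came from the GENCODE M21 annotation of the same build, in which 16695 gene identifiers matched and 53 did not. 22 identifiers had no symbol, and 10 symbols had 2 identifiers, in which case the one with the higher mean stands for the symbol in a list. The limma step was tested on simulated counts for the NOD against C57BL6 comparison over 16748 genes, of which 200 were changed. It recovered 36% of the genes changed 1.5-fold, 80% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold, and 15 of its 171 calls were false, above the nominal 5%. In the simulation camera and fry each called the 1 shifted list and 0 of the others. The simulated genes were drawn independently of each other, so this does not test lists whose genes vary together. The alternatives were quantile normalization, scaling to the library total, limma without the trend, other filters, a pseudocount of 0.1, other thresholds, removal of strain-divergent gene families, a replicate block and leaving out each library. Chosen after the values were seen were count tests on the recovered reads (edgeR 4.0.16, DESeq2 and limma-voom) and leaving out 3 libraries together, C57BL6 replicate 6 and NOD replicate 4 for their place on the second principal component and NOD replicate 3 for its reads in the repeat-derived gene Gm10800. edgeR with TMM factors called 4021 genes higher and 3728 lower, and DESeq2 4058 and 3716. The replicate correlations were computed on log2 values. No pair of libraries of a strain was alike within sampling noise, with a chi-square per degree of freedom of 5.54 to 21.8, so all 8 were kept.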

Results

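The transcriptomes of enriched spleen NK cells were compared between NOD and C57BL6 mice, to find how the NK cells of the 2 strains differ. Each strain contributed 4 libraries, with 8541693 to 14961466 recovered reads over the 16748 listed genes. Log2 values correlated at r = 0.977 to 0.988 between libraries of a strain and at 0.882 to 0.912 between strains, across genes, which are not independent replicates. The first principal component held 78.7% of the variance and separated the strains. On the second, with 6.3%, C57BL6 replicate 6 stood at -42.4 and the other C57BL6 libraries between 6.8 and 21.1. That library also had 1.35% of its reads in mitochondrial genes, against 0.622% to 0.783% in the other C57BL6 libraries and 0.954% to 1.1% in NOD.

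In NOD libraries most transcripts that identify NK cells were lower, as were those of perforin and of granzymes A and B, and markers of dendritic cells, macrophages, granulocytes, platelets and plasma cells were higher. In all, 4083 genes were higher in NOD and 3715 were lower, 46.6% of those tested (limma, adjusted p under 0.05). Changes of at least 2-fold were found for 2184 higher and 727 lower genes, and of at least 8-fold for 358 and 98. The strains did not overlap for 7268 genes, or 43.4%, where chance gives 2.86%. Of the called genes 52.4% were higher ones, and this balance depended on the scaling. It was 63.4% with library totals (4726 higher, 2733 lower) and turned to 42.8% with quantile normalization (3595 higher, 4808 lower). The median of all genes on the log2 scale was -0.01, 0.09 with library totals and -0.11 with quantile normalization. The authors' deposited table has 4058 genes higher and 3716 lower at the same threshold, of which 7640 were called here in the same direction and 0 in the opposite one. Of the 36 lists 13 were called higher and 8 lower by camera, and none of these calls held with an estimated correlation, where 5 lists were higher and 0 lower at an unadjusted p under 0.05. By fry 15 lists were higher and 12 lower.

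Genes that identify NK cells fell in NOD. Ncr1, which encodes the activating receptor NKp46 used to check the enrichment, averaged 6613 ± 1410 normalized counts in C57BL6 and 2859 ± 214 in NOD (SD, n = 4 each, log2 fold change -1.19 ± 0.13, limma adjusted p = 5.17e-06). Itga2, which encodes CD49b, fell by 0.80 on the log2 scale. Klrb1c, the NK1.1 receptor gene, fell from 7208 ± 1260 to 1299 ± 149 (log2 fold change -2.46 ± 0.12, limma adjusted p = 4.38e-09). The transcription factors Tbx21 and Eomes, which maintain NK cells, fell by 1.20 and 0.79, and the activating receptor gene Klrk1 by 1.12 on the log2 scale, and for these 6 genes the 4 NOD libraries were all below the 4 C57BL6 libraries. Of 23 measured genes of the NK identity list 20 were lower, 1 was higher and 2 did not pass, the same counts as when adjusted over the list alone, with a median of -0.79 (camera adjusted p = 9.16e-09). With an estimated correlation this list had an adjusted p = 0.322. Of these genes 16 are also in other lists. The exception was the adhesion molecule gene Ncam1, at 2.62 ± 0.746 in C57BL6 and 41.8 ± 12.1 in NOD. Outside chromosome 6, which holds the NK receptor gene complex, 15 of 18 members were lower and 1 higher, with a median of -0.71. Cd3e, a T cell gene whose protein was to be absent, was higher in NOD (303 ± 106 against 689 ± 231, log2 fold change 1.18 ± 0.26, limma adjusted p = 0.00213), with overlapping strains.

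**Figure D1:**
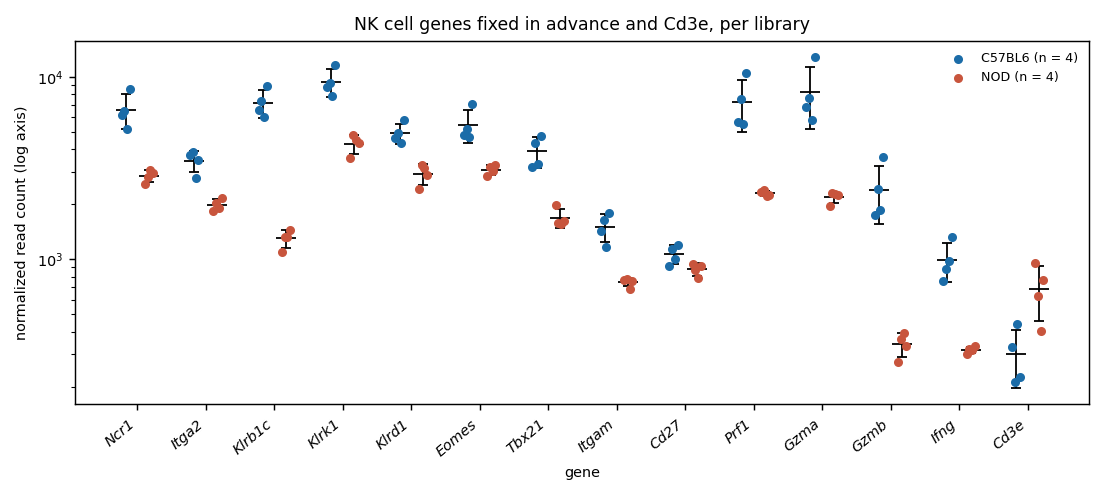
Normalized read counts (log axis) of the 14 genes named whatever their values, with 1 point per library and the mean ± SD of 4 libraries as black bars. For Ncr1 the C57BL6 libraries average 6613 and the NOD libraries 2859, while Cd3e averages 303 and 689.

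Genes of mature NK cells fell about as much as NK identity genes (medians -0.90 and -0.79), and genes of the ILC1 and tissue-resident list rose. Of 16 mature NK genes 12 were lower and 2 higher (median -0.90, camera adjusted p = 0.000149, and adjusted p = 0.434 with an estimated correlation). Itgam, which encodes CD11b, fell by 0.99, S1pr5, a receptor for exit from lymphoid tissue, by 1.60, and the terminal maturation marker Klrg1 by 1.67 on the log2 scale, while S100a4 and Cx3cr1 rose by 2.01 and 0.96. The immature NK list held 6 higher and 7 lower genes of 16 and was not called (adjusted p = 0.884). Its median was -0.06 and its mean 0.14. Cd27, a marker of less mature NK cells, was at 1067 ± 128 in C57BL6 and 877 ± 69.6 in NOD (log2 fold change -0.28, limma adjusted p = 0.0328). That call was lost without C57BL6 replicate 3 (0.0968) or 6 (0.0732) or NOD replicate 3 (0.0711) or 4 (0.0965), and also with the replicate block (0.128), library totals (0.134), limma without trend (0.0809), edgeR without factors (0.135) and 3 libraries left out (0.36). The range over 22 alternatives was 0.0118 to 0.36, and 13 of them kept the call. Of 17 ILC1 and tissue-resident genes 12 rose and 0 fell (median 1.13, camera adjusted p = 9.3e-05, and adjusted p = 0.212 with an estimated correlation), among them Itga1, which encodes CD49a (1.80), and Tmem176b (2.53). Of the 17 genes 10 are also in other lists, and markers of ILC2 and ILC3 (median 1.45), dendritic cells (1.95) and macrophages (1.16) rose in the same libraries, so the source cells of this rise are not resolved. The counts of these 3 lists were the same adjusted over the list alone. Per library, the mature list minus the immature list was 1.01 ± 0.23 in C57BL6 and 0.07 ± 0.04 in NOD, a difference of -0.94 in log2 units (exact permutation test, 2-sided p = 0.0286, the smallest that 4 against 4 allows). Among its 6 higher and 7 lower genes the immature list includes Cd93, also a progenitor marker, which rose by 3.28. This difference can therefore include other cells and does not single out maturation.

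Genes for the main cytotoxic molecules, perforin and the granzymes A and B, fell, while other granule genes changed less or rose. Granzyme B (Gzmb) averaged 2406 ± 857 in C57BL6 and 342 ± 52.4 in NOD (log2 fold change -2.76 ± 0.19, limma adjusted p = 1.28e-07). Granzyme A (Gzma) fell by 1.86 and perforin (Prf1) by 1.62 on the log2 scale, while Gzmk was higher by 1.81. Of 20 cytotoxic granule genes 11 were lower and 4 higher, or 12 and 5 adjusted over the list alone (median -0.57, camera adjusted p = 0.0495). This call was lost with an estimated correlation (adjusted p = 0.696), under quantile normalization (0.187), and without C57BL6 replicate 6 (0.0558) or NOD replicate 2 (0.0969), in a range of 0.0196 to 0.187 over 13 alternatives. Interferon gamma (Ifng) fell from 986 ± 241 to 318 ± 13.4, and the chemokine gene Ccl5 by 2.05 on the log2 scale, while Il18 rose from 29.3 ± 5.82 to 84.1 ± 13.2 and Il1b by 1.34 on the log2 scale. The cytokine list as a whole held 9 higher and 8 lower genes of 20 (9 and 9 adjusted over the list alone) and was not called (adjusted p = 0.946, median -0.07, mean 0.15).

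Receptor families of the NK complex changed in both directions. Ly49 receptors, which bind MHC class I, gave 4 higher and 7 lower genes of 13 (the same adjusted over the list alone). Klra17 rose from 11.2 ± 1.34 to 838 ± 202 and Klra1 from 368 ± 99.2 to 4822 ± 723, whereas Klra3 fell from 822 ± 186 to 38.8 ± 12.3. The Ly49 list was not called (camera adjusted p = 0.0696, median -1.04, mean -0.25), but it was without C57BL6 replicate 4 (0.0315) or NOD replicate 5 (0.0472) with library totals (0.0265) and with 3 libraries left out (0.0423), in a range of 0.0265 to 0.159 over 13 alternatives. Of 20 NKG2 and NKR-P1 genes 11 were lower and 6 higher, also adjusted over the list alone, with Klrc2 down from 5039 ± 812 to 374 ± 68.3 and Klrc1, the inhibitory NKG2A gene, down by 2.11 on the log2 scale. That list (camera adjusted p = 0.0545) was called lower without C57BL6 replicate 4 (0.0274) and without NOD replicate 3 (0.0329), 4 (0.0314) or 5 (0.0482), and also with library totals (0.0196) and with 3 libraries left out (0.012), in a range of 0.012 to 0.158. Genes in these families are close in sequence, and their values are uncertain because the counting of shared reads is not given in the sources used here. Dendritic cell and macrophage markers (medians 1.95 and 1.16) rose in the same libraries, so the source cells of higher genes such as Klra17 are not resolved.

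Signalling and regulatory genes of lymphocytes fell on balance. Of 31 activating signalling genes 19 were lower and 7 higher, also adjusted over the list alone (median -0.40, camera adjusted p = 0.0052, and adjusted p = 0.556 with an estimated correlation). Cd247, which encodes the CD3 zeta chain, fell by 1.47 and the kinase gene Lck by 1.08, while Crtam rose by 1.39 on the log2 scale. Of 37 lymphocyte transcription factors 15 were lower and 4 higher, also adjusted over the list alone (median -0.23, camera adjusted p = 0.0116, and adjusted p = 0.274 with an estimated correlation). Both calls were lost under quantile normalization (0.125 and 0.22), in ranges of 0.00227 to 0.125 and 0.0058 to 0.22. Inhibitory receptors gave 12 higher and 5 lower genes of 24 (6 lower adjusted over the list alone), with Havcr2, which encodes TIM-3, up by 2.36, and were not called (adjusted p = 0.0743). They were called higher under quantile normalization (0.0454) and with 3 libraries left out (0.0287), in a range of 0.0287 to 0.114. The cytokine receptor list (10 higher, 15 lower of 32, and 17 lower adjusted over the list alone) and the migration list (9 higher, 12 lower of 28, and 10 and 13 adjusted over the list alone) were not called, with adjusted p of 0.176 and 0.177. In the first, the interleukin 12 receptor genes Il12rb1 and Il12rb2 fell by 1.65 and 1.16 while Il6ra rose by 1.90 on the log2 scale, and its median (-0.22) and mean (0.02) differed in sign. Il6ra is also in the basophil and mast cell list. Macrophage and dendritic cell markers (medians 1.16 and 1.95) rose in the same libraries, so the source cells of the higher receptor genes are not resolved.

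MHC class I genes changed in both directions, while most class II genes rose. Of 35 class I and antigen processing genes 21 were lower and 9 higher, or 22 and 9 adjusted over the list alone (median -0.54, camera adjusted p = 0.00126, and adjusted p = 0.556 with an estimated correlation). The mean was -0.11, the list means of the strains overlapped, and with a GC and length trend removed the median was -0.34. The class I genes H2-K1 and H2-D1 fell by 1.35 and 0.91 and the nonclassical gene H2-Q7 from 7815 ± 924 to 1289 ± 91.7, whereas H2-Q2 rose from 2.05 ± 2.17 to 241 ± 17.1. H2-Ke6, which is in the list by its symbol and encodes a dehydrogenase, fell by 1.12. Of 19 measured class I genes with H2 symbols 8 were higher and 10 lower. Loss or misplacement of NOD reads against the reference cannot be told apart from a change of expression for them. Of 11 class II genes 8 rose and 0 fell, also adjusted over the list alone, with H2-Ab1 up from 1918 ± 518 to 6531 ± 632 (median 0.90, camera adjusted p = 0.00183, and adjusted p = 0.556 with an estimated correlation). Dendritic cell and macrophage markers, which come from cells that carry class II, rose in the same libraries. Of 65 interferon-stimulated genes 32 were lower and 8 higher, or 33 and 9 adjusted over the list alone (median -0.41, camera adjusted p = 0.000743, and adjusted p = 0.696 with an estimated correlation). Ifi213 fell by 4.86 and Gbp4 by 1.09 on the log2 scale. The list means of the strains overlapped here too. C57BL6 replicate 6 had the highest mean of this list, 8.78 against 8.29 to 8.35 in the other C57BL6 libraries, and of the class I list, 9.37 against 9.04 to 9.07.

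**Figure D2:**
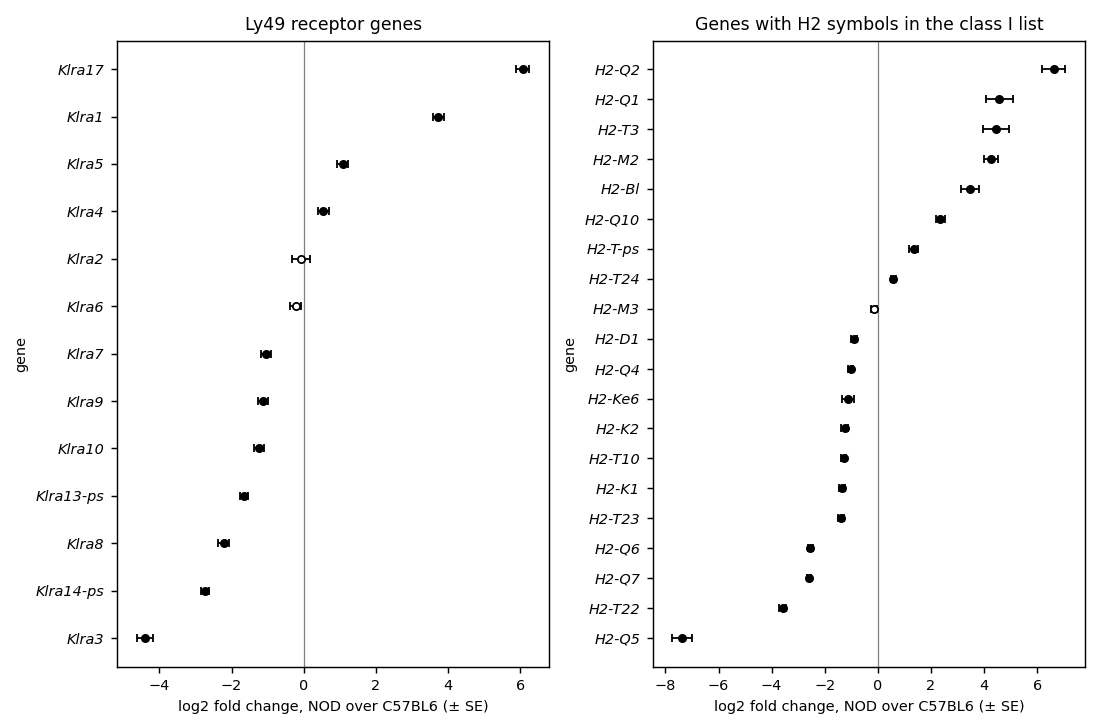
Log2 fold change of NOD over C57BL6 (± SE, 4 libraries per strain) for the Ly49 genes and for the genes with H2 symbols in the class I list, filled where the limma adjusted p was under 0.05. Klra17 (6.07) and H2-Q2 (6.62) stand at the top, Klra3 (-4.40) and H2-Q5 (-7.37) at the bottom.

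Among 24 genes named in NOD diabetes susceptibility loci 15 were higher and 7 lower, also adjusted over the list alone (median 0.63, camera adjusted p = 0.0378, and adjusted p = 0.284 with an estimated correlation). Sirpa, which encodes an inhibitory receptor of myeloid cells, rose from 723 ± 30.0 to 2880 ± 165 and Cd93 from 169 ± 26.5 to 1649 ± 270, while the costimulatory receptor gene Tnfrsf9 fell by 2.48 on the log2 scale. Cd93 is also a progenitor marker, and macrophage, dendritic cell and progenitor markers (medians 1.16, 1.95 and 0.88) rose in the same libraries. The list shares 15 of its 24 genes with other lists. Its call was lost without C57BL6 replicate 2 (0.0509) or 6 (0.0531) or NOD replicate 3 (0.0516), with library totals (0.0776), with the replicate block (0.0547) and with 3 libraries left out (0.0561). The range over 13 alternatives was 0.00859 to 0.0776, and 7 of them kept the call. Fc and complement receptors gave 6 higher and 7 lower genes of 18 (7 and 7 adjusted over the list alone) and were not called (adjusted p = 0.838, median -0.03, mean 0.19). The inhibitory Fc receptor gene Fcgr2b fell by 1.21 and complement C3 rose by 2.42 on the log2 scale.

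Markers of most other blood cell types were higher in NOD. Of 23 dendritic cell markers 20 rose and 1 fell (median 1.95, camera adjusted p = 6.26e-09, and adjusted p = 0.212 with an estimated correlation). Flt3, a growth factor receptor gene of dendritic cells and progenitors, rose from 133 ± 20.5 to 1157 ± 149, and Siglech, a plasmacytoid dendritic cell marker, from 130 ± 70 to 2882 ± 918. The most abundant were Wdfy4 (2734 ± 971 and 6345 ± 867) and Tcf4 (1515 ± 214 and 5748 ± 1380), and 5 of the 23 genes are also in other lists. The exception was Ly6d, which fell by 2.12. Of 26 monocyte and macrophage markers 19 rose and 1 fell, or 20 and 1 adjusted over the list alone (median 1.16, camera adjusted p = 5.18e-07, and adjusted p = 0.14 with an estimated correlation), with Lyz2, which encodes lysozyme, at 2231 ± 96.2 and 13880 ± 2390. Neutrophil markers (14 of 17 higher and 0 lower, 16 adjusted over the list alone, median 1.76) had a camera adjusted p = 1.72e-06, and adjusted p = 0.274 with an estimated correlation. Basophil and mast cell markers (12 of 13 higher and 0 lower, median 1.65) had 2.63e-06, and adjusted p = 0.29 with an estimated correlation. Megakaryocyte and platelet markers (16 of 17 higher and 0 lower, median 1.57) had 2.75e-06, and adjusted p = 0.556 with an estimated correlation. The von Willebrand factor gene Vwf rose from 726 ± 176 to 3233 ± 1210. All 11 plasma cell markers in the table, of 13 in the list, were higher (median 1.73, camera adjusted p = 0.000316, and adjusted p = 0.284 with an estimated correlation), with Igha at 226 ± 280 and 1851 ± 420. The C57BL6 mean of Igha rests on replicate 4 (640 against 47.7 to 160 in the others), without which its log2 fold change was 4.56. The counts not given for the list alone were the same when adjusted over the list alone.

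Smaller marker groups moved the same way, while lymphocyte markers were not called as lists. Stromal and endothelial markers (all 9 in the table higher, of 20 in the list, median 1.95, camera adjusted p = 0.0004, and adjusted p = 0.212 with an estimated correlation) included the vascular receptor gene Kdr, up by 2.74. Haematopoietic progenitor markers (12 of 16 higher and 2 lower, median 0.88, camera adjusted p = 0.000995) had an adjusted p = 0.274 with an estimated correlation. ILC2 and ILC3 markers (9 of 13 higher and 2 lower, median 1.45, camera adjusted p = 0.0188) had an adjusted p = 0.274 with an estimated correlation. Erythroid markers (14 of 23 higher and 2 lower, 16 and 2 adjusted over the list alone, median 0.84, camera adjusted p = 0.0045, and adjusted p = 0.611 with an estimated correlation) held the near-identical globin genes Hba-a1, which rose from 294 ± 153 to 897 ± 595 with overlapping strains, and Hba-a2, which fell from 84.5 ± 61.5 to 1.33 ± 1.95, and whose reads can be shared. The erythroid list means of the strains overlapped. T cell markers gave 8 higher and 3 lower genes of 21, also adjusted over the list alone, and were not called (adjusted p = 0.121), but were called higher without C57BL6 replicate 4 (0.0267) or NOD replicate 4 (0.0314) and with 3 libraries left out (0.0255), in a range of 0.0255 to 0.211. B cell markers gave 2 higher and 4 lower genes of 23, or 1 and 4 adjusted over the list alone, and were not called (adjusted p = 0.354). Without NOD replicate 2, in which their mean was 10.05 against 9.05 to 9.15 in the other NOD libraries, they were called lower (0.0219), in a range of 0.0219 to 1. The stromal, progenitor and ILC2 and ILC3 counts were the same adjusted over the list alone.

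**Figure D3:**
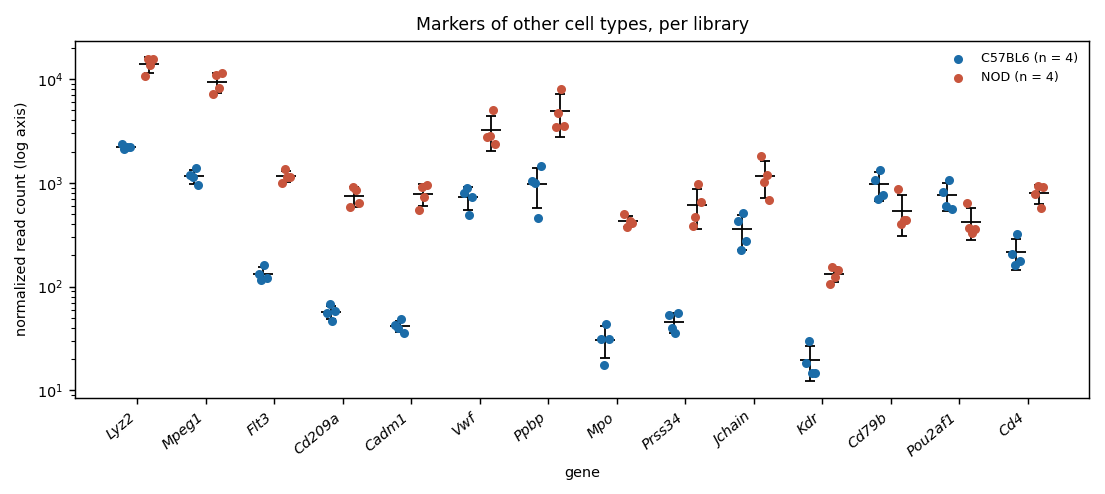
Normalized read counts (log axis) of markers of other cell types, with 1 point per library and the mean ± SD of 4 libraries as black bars. Lyz2 averages 2231 in C57BL6 and 13880 in NOD, whereas the B cell gene Cd79b averages 964 and 537 with overlapping strains.

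Genes for cytosolic ribosomal proteins fell together: 56 of 78 were lower and 1 higher, or 58 and 1 adjusted over the list alone (median -0.46, camera adjusted p = 1.31e-10, and adjusted p = 0.556 with an estimated correlation). Rpl29 fell from 2741 ± 492 to 453 ± 43.3. C57BL6 replicate 6 had a list mean of 11.19 against 10.62 to 10.83 in the other C57BL6 libraries, and without it the median was -0.336. The other lists of general cell state were not called. Proliferation genes gave 2 higher and 6 lower of 31, or 2 and 3 adjusted over the list alone (adjusted p = 0.738, median -0.01, mean 0.01). Immediate-early and handling stress genes gave 15 higher and 11 lower of 39 (adjusted p = 0.354, and 0.0112 under quantile normalization, in a range of 0.0112 to 0.741), in which Klf4 rose by 1.39 and Atf3 by 1.42, while of its heat shock genes, which were not a list of their own, Hspa1b fell from 7659 ± 3970 to 2216 ± 1500, Hspa1a by 1.65, Hsph1 by 1.25 and Dnajb1 by 0.98 on the log2 scale, and Hsp90aa1 (-0.06) and Dnaja1 (-0.16) did not pass. Glycolysis genes gave 5 higher and 5 lower of 23 (adjusted p = 0.884), with Hk2 up by 1.56 and Pfkp down by 0.98 on the log2 scale. Apoptosis and survival genes gave 12 higher and 9 lower of 33, or 12 and 11 adjusted over the list alone (adjusted p = 0.544, median -0.01, mean 0.39), with the inflammasome gene Nlrp3 up from 251 ± 25.3 to 938 ± 177. Of 8 mitochondrially encoded genes 0 were higher and 1 lower (adjusted p = 0.916, median 0.22, mean -0.30), and the list was called higher without C57BL6 replicate 6 (0.026) and with the replicate block (0.0259), in a range of 0.0259 to 0.994. Its median ranged from 0.019 without C57BL6 replicate 4 to 0.5 without C57BL6 replicate 6. The stress, glycolysis and mitochondrial counts were the same adjusted over the list alone.

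**Figure D4:**
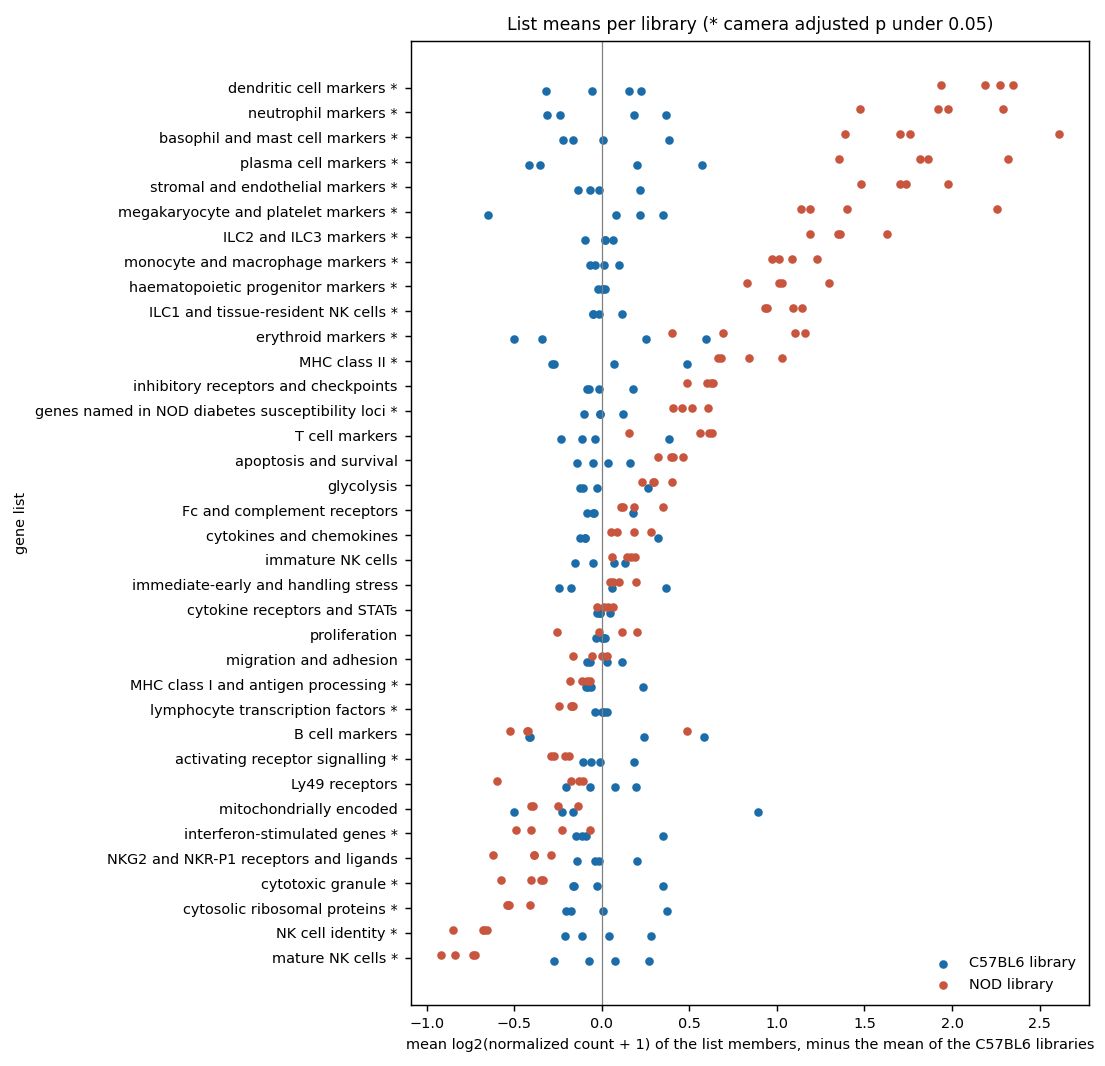
Mean log2(normalized count + 1) over the members of each of the 36 lists, 1 point per library, minus the mean of the C57BL6 libraries, with a star where the camera adjusted p was under 0.05. The dendritic cell list stands highest and the mature NK list lowest in NOD, and the B cell list has NOD and C57BL6 points that overlap.

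The genes with the largest fold changes in either direction had few or no reads in 1 strain. Loss or misplacement of NOD reads against the reference, or different gene content, was not tested for them. Tpm3-rs7 (ENSMUSG00000058126, chromosome 14, 113314608 to 113316754 in mm10) averaged 3.55 ± 2.56 in C57BL6 and 4850 ± 381 in NOD (log2 fold change 10.26 ± 0.33, limma adjusted p = 1.69e-10). Npy, which encodes neuropeptide Y, had 0 reads in all C57BL6 libraries and 317 ± 155 in NOD, at least 457-fold higher. The interferon-inducible gene Ifi202b and the lectin gene Itln1 also had 0 reads in C57BL6 and were at least 246-fold and at least 176-fold higher. St6galnac1, a sialyltransferase gene, had 1 read in C57BL6 and 1516 in NOD, a count ratio of 1820 (95% interval 327 to 72100). The other genes of the highest 12 were Zfp990, Hist1h2al, Eif3j2, Zfp979, Ear1, Vsx1 and A2ml1, with log2 fold changes of 6.80 to 9.21.

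In the other direction, Trim12a (ENSMUSG00000066258, chromosome 7, 104299894 to 104315466) averaged 1828 ± 96.2 in C57BL6 and had 2 reads in NOD, a count ratio of 3370 (95% interval 933 to 27800). Khdc1a had 0 reads in NOD and was at least 436-fold lower there. H2-Q5 fell from 1777 ± 249 to 11.4 ± 6.82 and Baiap3, which takes part in vesicle release, from 2426 ± 452 to 18.9 ± 9.85. The other 8 were Khdc1c, Gsta3, Khdc1b, Eps8l1, Zfp125, Klrb1, Hba-a2 and D5Ertd615e, with log2 fold changes of -6.50 to -5.18. In all, 18 genes had 0 reads in every C57BL6 library and 17 in every NOD library. Predicted genes and those without a usual symbol made up 913 of the higher and 536 of the lower genes.

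**Figure D5:**
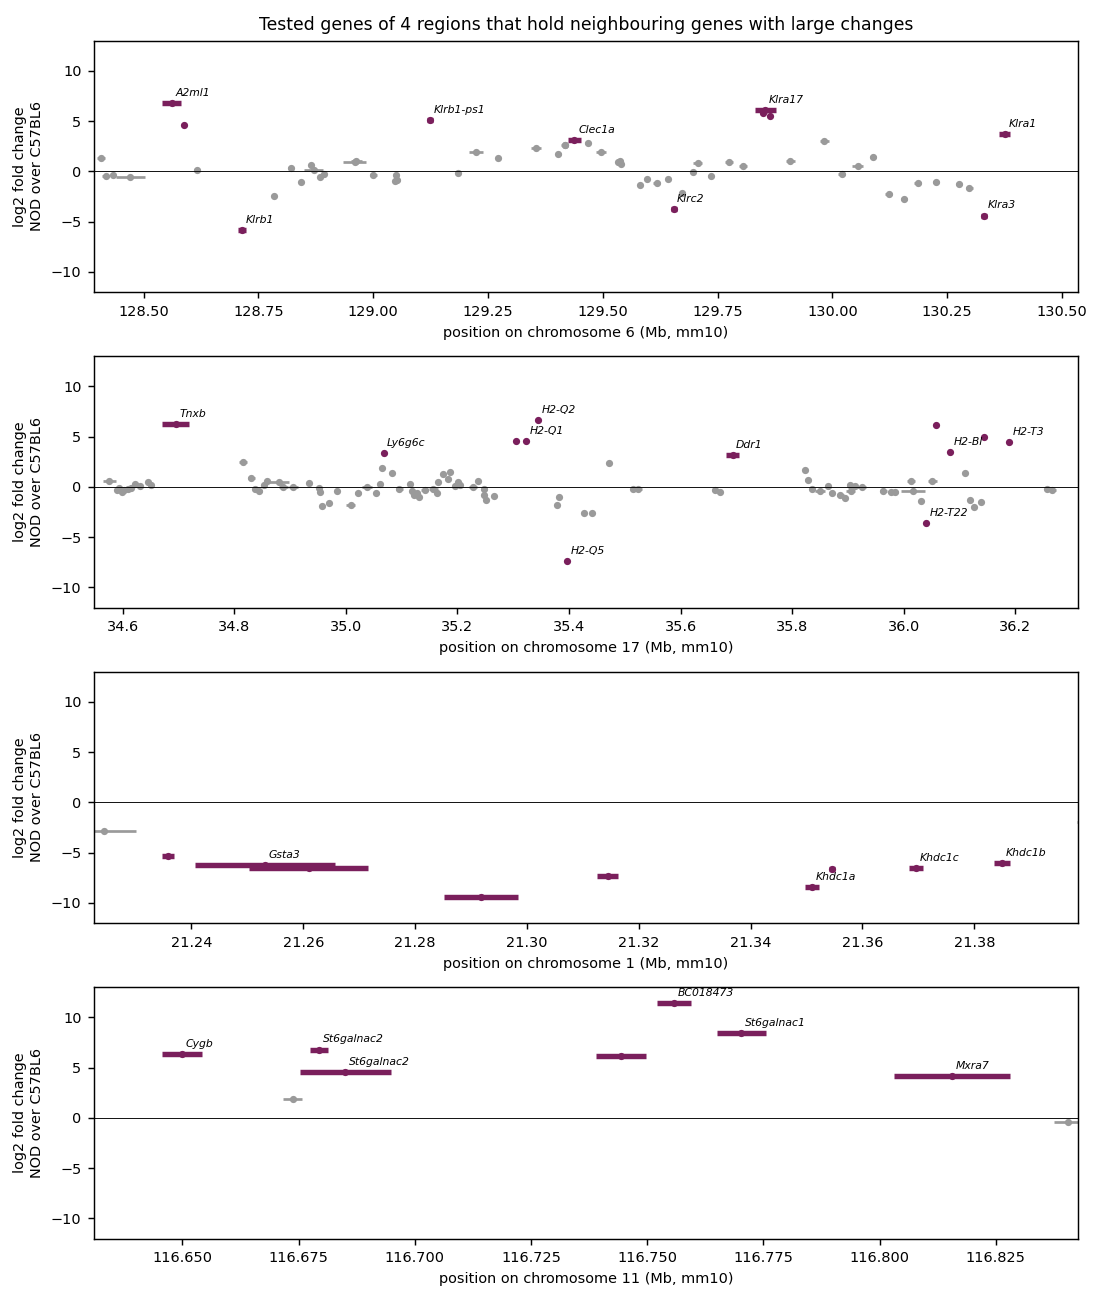
Log2 fold change of each tested gene against its position (Mb, mm10) in 4 regions, with each gene as a bar over its span and a point at its centre, purple for members of the region's group of called genes with a change of at least 3 in log2 units. On chromosome 1 the Khdc1 and Gsta3 genes are all lower in NOD, on chromosome 11 the St6galnac genes and their neighbours are higher, and on chromosomes 6 and 17 genes of both directions stand side by side.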

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

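A library counted as far from the other 3 of its strain when its gap to the nearest of them, divided by the range, was above Dixon's 95% critical value. This was applied to the named genes, the list means and the library totals and shares, 394 groups of 4, of which chance flags about 1 in 20 (19.7) and 31 were found. 8 of the 31 were in C57BL6 replicate 6.

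C57BL6 replicate 6 stood above the other C57BL6 libraries in Id2 (5299 normalized counts against 2968 to 3218), Klra1 (516 against 313 to 323) and Zfp979 (5.65 against 1.46 to 1.95). In log2 list means it stood above them for cytokines and chemokines (8.48 against 8.03 to 8.06), class I and antigen processing (9.37 against 9.04 to 9.07), interferon-stimulated genes (8.78 against 8.29 to 8.35) and Fc and complement receptors (8.40 against 8.14 to 8.18). The small nuclear RNA gene Rn7sk took 3.02% of its reads against 2.06% to 2.19%.

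NOD replicate 2 had more of the B cell genes Cd79b (880 against 397 to 439) and Pou2af1 (637 against 326 to 370), a higher B cell list mean (10.05 against 9.05 to 9.15), and lower means of the NK identity list (10.42 against 10.59 to 10.61) and the Ly49 list (8.5 against 8.92 to 8.99). Its Tbx21 value was 1977 against 1566 to 1615, and its Gzma value was 1948 against 2237 to 2294. NOD replicate 4 had Pf4 at 744 against 298 to 327, a T cell list mean of 7.78 against 8.19 to 8.26 and a ribosomal protein list mean of 10.41 against 10.28 to 10.29.

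Among the other C57BL6 libraries, replicate 2 had Sirpa at 768 against 705 to 710 and Adgre1 at 259 against 213 to 220. Replicate 4 had Itgb3 at 701 against 961 to 1013, and Gm26917 took 5.96% of its reads against 4.46% to 4.6%. The remaining ones rest on a few reads in 1 library and 0 in the other 3: St6galnac1 at 0.866 and Ear1 at 1.73 in C57BL6 replicate 4, Hist1h2al at 2.92 and Vsx1 at 1.95 in C57BL6 replicate 2, Eif3j2 at 1.46 and Klrb1-ps1 at 0.732 in C57BL6 replicate 3, Khdc1c at 1.07 in NOD replicate 5, and Khdc1b at 2.11 and mt-Nd3 at 1.06 in NOD replicate 3.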

How the results depend on the processing

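The count tests and the fits without 3 libraries were chosen after the values were seen. Of 3390 alternative values of named genes 3373 kept their direction and side of the threshold, 17 lost the call (Mcm4, Ccnb2, Ccnb1, Cd79b and Cd27) and 0 reversed. Of 468 alternative values of lists 403 kept both, 11 lost a call, 19 gained one and 35 were counted as a median of another sign, none of these in a called list. The 35 include glycolysis values of either sign, although its median with all libraries was 0 and had no sign to change. Camera's own direction turned in 19 cases, also in lists that were not called. At a fold of at least 2 the counts were 2184 higher and 727 lower, and at adjusted p under 0.01 they were 3107 and 2458, by the stricter rules alone. Camera with an estimated correlation called 0 lists higher and 0 lower, against 13 and 8, and fry, which does not compare a list with other genes, 15 and 12. Quantile normalization left 5 lists lower, and the cause was not tested.

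Leaving out each library in turn gave 3555 to 3994 genes higher and 3098 to 3633 lower, with 12 to 14 lists higher and 7 to 10 lower. Without C57BL6 replicate 6 and NOD replicates 3 and 4 together, 3301 were higher and 2696 lower. Of these 3185 and 2548 were among the genes of the fit with all libraries. The replicate block over the numbers 2, 3 and 4 gave 3455 and 2654 genes, with 13 and 8 lists. It lost the susceptibility list (0.0547) and gained the mitochondrial list (0.0259), but the block leaves out C57BL6 replicate 6 and NOD replicate 5, and without C57BL6 replicate 6 alone both moves were also seen (0.0531 and 0.026). Deviations of libraries with the same number correlated at 0.014, -0.052 and -0.145, and none of the libraries numbered 2, 3 or 4 correlated best with its own number.

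The medians counted as changed in sign belonged to 6 lists, and the cause was not tested. One of these lists was glycolysis, whose median in the main fit was 0, so its values moved off 0 rather than across it. With library totals they were 0.034 for immature NK cells, 0.027 for cytokines, 0.062 for Fc receptors, 0.088 for proliferation, 0.096 for glycolysis and 0.084 for apoptosis. With the block they were 0.044 for cytokines, 0.213 for Fc receptors, 0.06 for glycolysis and 0.111 for apoptosis, and quantile normalization gave -0.021 for glycolysis. Without the 3 libraries they were 0.087 for cytokines, 0.272 for Fc receptors, 0.074 for proliferation, 0.097 for glycolysis and 0.002 for apoptosis. Leaving out single libraries gave -0.153 to 0.017 for cytokines, -0.253 to 0.127 for Fc receptors, -0.08 to 0.106 for proliferation, -0.051 to 0.092 for glycolysis and -0.06 to 0.095 for apoptosis.

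Fold changes correlated across genes with GC content (Spearman's rho -0.218) and length (0.086). With that trend removed, the medians of called lists kept their sign. They went from -0.79 to -0.93 for NK identity and from 1.95 to 2.15 for dendritic cells, but shrank from -0.54 to -0.34 for class I, from -0.46 to -0.33 for ribosomal proteins, from 1.13 to 0.88 for ILC1 and from -0.23 to -0.17 for transcription factors. Of lists not called, the sign turned for immature NK cells (0.02), cytokines (0.06), Fc receptors (0.22), proliferation (0.05) and mitochondrial genes (-0.08). The simulation recovered 36% of genes changed 1.5-fold, so small changes can be missed.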

Other observations

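The comparisons of dendritic with B cell markers and of the cytotoxic granule list with the NK identity list, those of reads lost against the reference for the Ly49 and class I members, that of chance placement and the count of neighbours with the same symbol stem were chosen after the results were seen.

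Genes with large changes (called, at least 3 in log2 units) formed runs in the genome, and the regions named here were chosen after their values were seen. On chromosome 1, from 21234722 to 21386373, all 9 tested genes were lower in NOD by that much, among them Gsta3 and Khdc1a, Khdc1b and Khdc1c. On chromosome 11, from 116645595 to 116828046, 7 of 8 tested genes were higher by that much, among them BC018473 (0.549 ± 1.1 and 3722 ± 440 normalized counts), Cygb (log2 fold change 6.37) and Mxra7 (4.18). On chromosome 1, from 173468485 to 174054752, the interferon-inducible Ifi200 family region held 16 tested genes, of which 4 were higher and 3 lower by at least 3 in log2 units, with Ifi202b and Ifi213 in opposite directions. The region of the NK receptor genes on chromosome 6, from 128539821 to 130386874, held 58 tested genes, of which 8 were higher and 3 lower by that much, and 28 higher and 21 lower among those called at any size. The MHC region on chromosome 17, from 34670535 to 36190287, held 88, of which 10 were higher and 2 lower by that much, while among those called at any size 25 were higher and 32 lower. By annotated class, 30.2% of 63 unprocessed pseudogenes, which arise by gene duplication, had a change of at least 8-fold in either direction, against 2.2% of 12612 protein-coding genes.

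The authors' deposited table has no p for 10 genes. 9 of them are predicted genes, and Gm10800 is the most abundant, with 25856 normalized counts in NOD replicate 3 against 244 to 1282 in the other NOD libraries, and 7668 in C57BL6 replicate 6 against 1402 to 3268. The tenth is the chemokine gene Cxcl10, with 155 in C57BL6 replicate 6 against 16.5 to 27.7 in the other C57BL6 libraries.

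Over the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 of 35, gave as many called genes, with 7798 against 0 at most in the others by limma (8884 against 2224 at most at an unadjusted p under 0.05). This argues against a chance division of these libraries only as far as 35 splits allow. The other splits mix the strains, which widens the spread within their groups, so few calls were to be expected there. A difference between pools or batches of the strains is not excluded, since the labels do not say that each library came from a separate animal.

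NK identity genes fell while markers of several other cell types rose in NOD. A lower share of NK cells with the other cells in unchanged proportions would raise all other markers alike. The dendritic cell list rose by 2.41 more in log2 units than the B cell list (exact permutation test, 2-sided p = 0.0286). The same difference for megakaryocyte markers was 1.72 with overlapping strains (exact permutation p = 0.0571). These comparisons were chosen after the values were seen, so their p-values cannot decide on this explanation. One dilution factor for all NK transcripts stays open. Relative to the identity list the whole cytotoxic granule list differed by 0.30 (exact permutation p = 0.0286), a smaller fall that decides nothing because other cells express several of its genes. Prf1, Gzma and Gzmb differed by -1.36 without overlap of the strains (exact permutation p = 0.0286). They were grouped after their values were seen, so this cannot decide the question either. Of 10000 random lists matched on expression, 0% had a median below the -0.79 of the identity list. The identity list thus fell beyond genes of like expression. This cannot decide on a loss of NOD reads alike across the genome, because the scaling removes such a loss. Loss at single loci was not tested. What stays open is a hypothesis of 2 parts. NOD samples may have held more dendritic, myeloid and other cells, and NOD NK cells may carry less cytotoxic mRNA per cell. Negative selection is meant to remove other cells, but their markers had reads in both strains. Lyz2 averaged 2231 in C57BL6 and 13880 in NOD, and Cd79b 964 and 537. Values from single cells, not used here, would be needed to decide.

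Members of the Ly49 and class I families changed in opposite directions. The 14 genes with Ly49 symbols, summed and taken relative to the NK identity list, were higher in NOD by 0.34 (exact permutation p = 0.0286). The sum itself changed by -0.38 with overlapping strains (exact permutation p = 0.0571). The relative value cannot decide on movement of reads among them. The identity list holds genes of the same complex, such as Klrb1c (log2 fold change -2.46), and the source cells of Klra17 are not resolved. For class I the sum of 19 genes with H2 symbols changed by -1.37 (exact permutation p = 0.0286), which argues against movement among those genes alone. Predicted genes were not summed, so movement of reads to them stays open. Of the called members 13 were higher with over 100 reads in NOD and 17 were lower. In both sets the loss or misplacement of NOD reads against the reference cannot be told apart from a change of expression, because no NOD sequence was used here. Different gene content of these loci in the strains, or reads from cells other than NK cells, may also contribute, and both were untested.

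Neighbouring genes shared large changes more than chance placement gives: of 450 such genes with a position 223 had another within 500 kb, against a mean of 147.6 in 10000 random draws (permutation p = 1e-04, the smallest they can give). Reads shared by overlapping genes are argued against as the sole origin, since with 1 gene kept per overlapping group 180 of 418 still had such a neighbour, against 124.1 (permutation p = 1e-04). Neighbouring members of gene families may account for the runs among named genes, of which 65 of 278 had a neighbour with another symbol stem, against 62.9 in random draws (permutation p = 0.4257), and 56 had one with the same stem, against 3. In tests on random genes the counts passed 0.05 in 2.5% to 4% of 200 sets. The count over all genes also passed in 100% of sets with planted runs of neighbouring genes. The other counts were not tested on planted sets, so the power of the count with another stem is not known. Strain differences in copy number or in shared regulatory sequence stay open and were untested.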
